A study of Homo sapiens with 6 samples.

How the data were processed

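The data were peak lists of ATAC-seq libraries from the human multiple myeloma line ARP1, 3 with a KDM6A knockout and 3 wild type, and each sample was placed in its group by its title. Per the labels, libraries were size selected and sequenced as read pairs of 150 bp on a NextSeq 500. Trimmomatic, FastQC, MultiQC, Bowtie2 and MACS2 2.1.2 are named in the submitters' processing notes, with the genome build GRCh38. The role, order and settings of these tools are not given in the sources used here. Nor is it given whether reads were shifted for the offset of Tn5 cuts or whether duplicates were removed. Each sample has its own list, so peaks were called per library and not on pooled samples, and the lists hold narrow peaks with a summit.

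Each peak in the deposited lists has a score, a fold enrichment, a −log10 p-value and a −log10 q-value, all as the authors' peak caller gave them. The deposited score is the −log10 q-value times 10 as a whole number. The fold, a ratio over background in the authors' lists, was used to describe or filter peaks within a list, and peaks were ranked by their −log10 p-value. Folds were also set between lists in the later checks of read depth and DNA copy number, and for the mitochondrial peak. Below a fold of 100, 100% of the deposited fold values of each list were whole multiples of a single step (tolerance 0.01 of a step), as (pileup + 1) over (background + 1) with a single background per library gives, so each library's background pileup was recovered from that step. Up to that fold no local background entered, and a segment with more DNA copies can then pass the threshold more often. Peaks numbered 33056 to 37315 per knockout list and 54444 to 56049 per wild-type list as deposited. The peak on the mitochondrial genome, 1 per list, was left out of all comparisons, and the rest lay on the primary chromosomes. Its fold ranged from 15157 to 17358, so mitochondrial reads were present when peaks were called. They may also count into the background pileup. Wilson intervals at the 95% level for shares of peaks cover counting error only.

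Gene positions came from a RefSeq gene table of GRCh38.p14 with the start and end of each gene and no strand. The planned promoter windows therefore became windows of 1 kb on either side of both gene ends of 20037 protein-coding genes, called gene ends here, and the regional windows reached 50 kb from either end. Promoters inside a gene record are missed by these windows. No genome sequence was used, so the planned motif and base composition tests were not run. Statements on which end is a gene's start are background knowledge. All 434 genes of the lists matched the table.

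The lists were merged where peaks shared at least 1 bp, and a region or gene end was called in a library when a peak of that library overlapped it. WT-only means 3 of 3 wild-type and 0 of 3 knockout lists, and KO-only the converse. Peak numbers, covered length and gene-end share were compared with two-sided exact permutation tests over the 20 labellings of the 6 libraries, whose smallest p is 0.1. Base-pair Jaccard indices were compared over the 10 distinct splits. Gene lists were tested with Fisher's exact test against genes, or regions near other genes, that could have been called, and chromosomes against the rest of the genome, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Regions are not independent replicates, so these tests describe the 6 libraries.

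The genes named were set by a rule written before the data were examined: 16 fixed genes (KDM6A, KDM6B, CD38, CD48, CIITA, NLRC5, HLA-DRA, CD74, SDC1, TNFRSF17, SLAMF7, IRF4, PRDM1, MYC, GAPDH and ACTB) with the WT-only and KO-only regions within 50 kb of them, the list genes with WT-only or KO-only ends, and the 10 further genes in each direction with the highest mean percentile of their peak. Alternatives set beforehand were a −log10 q-value of at least 5, equal list length, autosomes only, leaving out each library, a replicate block, windows of 500 bp, 10 kb and 100 kb, other overlap and presence rules and strata of peak strength. A fold of at least 4 in every list, windows of 2 kb, exclusion of 48 bins of 1 Mb with a mean of 60 or more peaks, and a requirement that the region itself be called in 1 genotype only were added after seeing the data. Runs of at least 2 such bins at most 5 Mb from each other numbered 11, and the segments of chromosomes 3, 4 and 11 were picked from them after their values were seen.

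The code was tested on simulated data. Pileups were drawn for the 39777 regions called in all 3 wild-type lists at each library's own background and threshold, with losses planted in the knockout. Of 200 regions with a 2-fold loss 15.5% were called WT-only, of 200 with a 4-fold loss 55.5%, and of the 39377 regions without a loss 0.11%. A planted 4-fold loss at 30 regions near cell cycle genes was found by the list test, and 1 of 19 lists passed. In the real lists 13.1% of regions near other genes were WT-only, against the 0.11% of simulated regions without a loss. The simulation therefore checks the code and not the power of the list test on the real lists. The tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.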

Results

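Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in ARP1, a human multiple myeloma cell line. Multiple myeloma is a cancer of antibody-secreting plasma cells. Cells in which KDM6A had been knocked out were compared with wild-type cells, with 3 libraries per genotype. KDM6A removes methyl groups from lysine 27 of histone H3, a mark of silenced chromatin, and is part of the KMT2C and KMT2D enhancer complexes. The question set by the submitters is how this protein regulates DNA accessibility in a myeloma line, in a series whose title concerns immunogenicity. The labels number the libraries as biological replicates without saying which cultures or clones they came from, so the p-values measure the spread between these 6 libraries.

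The depth behind the lists differed between genotypes. The labels aim at the same number of reads, 150 bp long, for every library. The background pileup that the peak caller worked against, recovered from the deposited fold values, was 2.31 ± 0.26 in the knockout and 3.52 ± 0.36 in the wild type (mean ± SD, n = 3), so that the knockout stood at 65.6% of the wild type. The weakest peak listed had a fold over background of 3.23 ± 0.12 in the knockout and 2.81 ± 0.10 in the wild type. A weak region was therefore harder to call in a knockout library than in a wild-type library, and this holds for every presence call given here.

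The targeted gene kept an accessible start in all libraries. KDM6A (chromosome X, 44873188 to 45112779, GRCh38) had a peak over its lower-coordinate end, where the gene is known to start, in 3 of 3 knockout and 3 of 3 wild-type lists, with a fold of 13.0 ± 1.86 in the knockout and 11.0 ± 2.44 in the wild type (SD, n = 3). Only 1 region within 50 kb of its ends was called in all 3 wild-type lists, and that region was called in all 6. An accessible start does not report whether the coding sequence was edited, so the peak lists do not check the genotype labels. KDM6B, the related demethylase of the same histone mark (chromosome 17, 7834217 to 7854796), also had a gene-end peak in all 6 lists, and none of its 4 wild-type regions within 50 kb was WT-only, though 1 of them, at 7851327 to 7852127, was called in only 2 knockout lists.

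Fewer regions were called accessible in the knockout, and most of the missing regions lay away from gene ends. Knockout libraries held 35475 ± 2188 peaks and wild-type libraries 54987 ± 919 (SD, n = 3), so that the knockout had 64.5% of the wild-type number. The peaks covered 32.7 ± 3.54 Mb in the knockout and 54.5 ± 2.39 Mb in the wild type. Every knockout library lay below every wild-type library in both measures, which gave a two-sided exact permutation p of 0.1, the smallest that 3 libraries against 3 allow. Peaks within 1 kb of an end of a protein-coding gene numbered 10522 ± 194 in the knockout and 11365 ± 147 in the wild type, a difference of 7.41%. They made up 29.7% ± 1.32 of the knockout peaks and 20.7% ± 0.55 of the wild-type peaks (exact permutation p = 0.1). In single libraries this share ranged from 20.1% (95% Wilson interval 19.7% to 20.4%) in wild-type replicate 3 to 31.2% (30.7% to 31.7%) in knockout replicate 1. When every list was shortened to its strongest 33055 peaks, the share differed by 1.10 percentage points in place of 9.04, and the covered length by −10.04 Mb in place of −21.8 Mb.

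**Figure D1:**
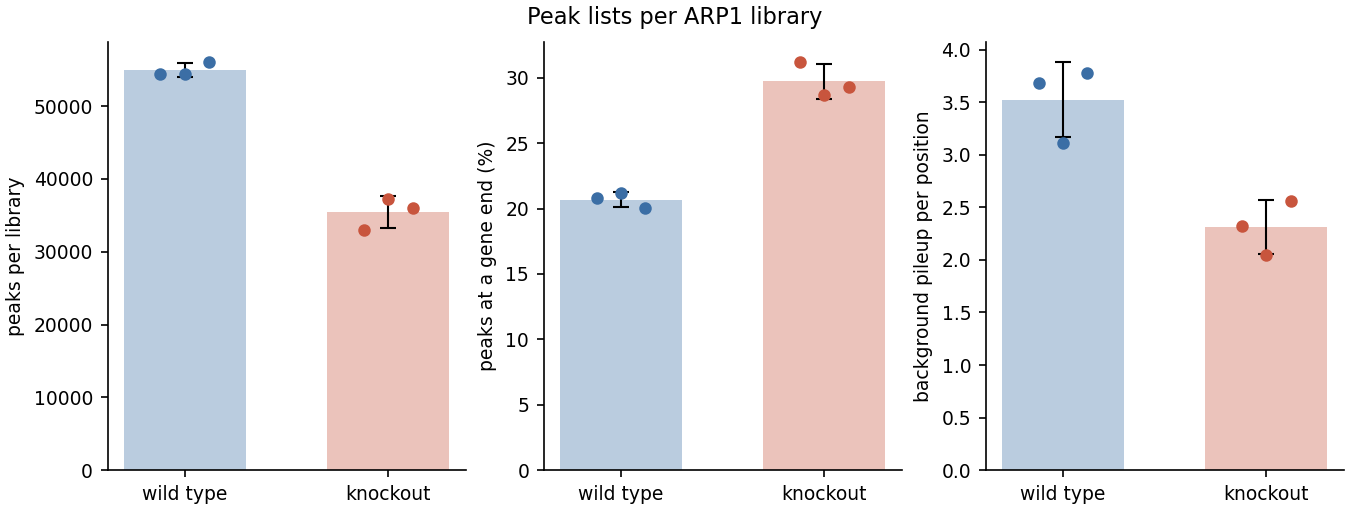
Peaks per library, percentage of peaks within 1 kb of a gene end, and background pileup per position for the 3 wild-type and 3 knockout libraries; points are libraries, bars are group means and error bars are SDs. Knockout libraries hold 33055 to 37314 peaks and wild-type libraries 54443 to 56048, while the knockout background pileup is 65.6% of that of the wild type.

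Peak lists overlapped more within a genotype than between genotypes. The base-pair Jaccard index, the shared length of a pair of lists over their joint length, averaged 0.602 among knockout lists, 0.638 among wild-type lists and 0.488 between genotypes. The mean within minus the mean between was 0.132, and the highest of the other splits of the 6 libraries gave 0.0024 (one-sided exact permutation p = 0.1, again the smallest possible). The lists covered 32.7 Mb in the knockout and 54.5 Mb in the wild type, and unequal lengths alone lower the index between genotypes. List length and genotype are therefore not told apart by this index. With lists of equal length the difference kept its direction, though covered length still differed.

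Regions missing from the knockout far outnumbered regions missing from the wild type. Merging the 6 lists gave 75701 regions, of which 23589 were called in all 6. WT-only regions, called in all 3 wild-type lists and in no knockout list, numbered 6871, or 17.3% of the 39777 regions called in all 3 wild-type lists. KO-only regions, called in all 3 knockout lists and in no wild-type list, numbered 95, or 0.39% of 24377. The KO-only count rose when any library was left out, since fewer lists then have to hold or lack a peak: leaving out knockout replicate 1, 2 or 3 gave 316, 219 and 242 regions, and leaving out wild-type replicate 1, 2 or 3 gave 157, 179 and 161. The numbers depended on the length of the lists: with the strongest 33055 peaks of each list, 1961 regions were WT-only and 906 KO-only, so that the WT-only part of both fell from 98.6% to 68.4%. WT-only regions were among the weaker wild-type regions, with a median fold of 5.27 against 11.98 for regions called in all 6. Of the 22545 regions that ranked in the top 50% of all 3 wild-type lists 778 were WT-only, of the 11268 in the top 25% 34 were, and of the 4215 in the top 10% none was.

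Gene ends were seldom WT-only. Of 10654 gene-end regions called in all 3 wild-type lists, 281 (2.64%) were WT-only, compared with 2809 of 12149 regions inside genes (23.1%) and 3781 of 16974 outside genes (22.3%). The odds of being WT-only were 10.8 times higher away from gene ends, and 4.28 times higher when regions were compared within 5 strata of wild-type peak strength (Fisher and Mantel-Haenszel tests across regions, which are not independent replicates). KO-only regions also lay mostly away from gene ends, with 4 of 9775 at a gene end and 91 of 14602 elsewhere (Fisher's exact p = 7.58e-16).

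**Figure D2:**
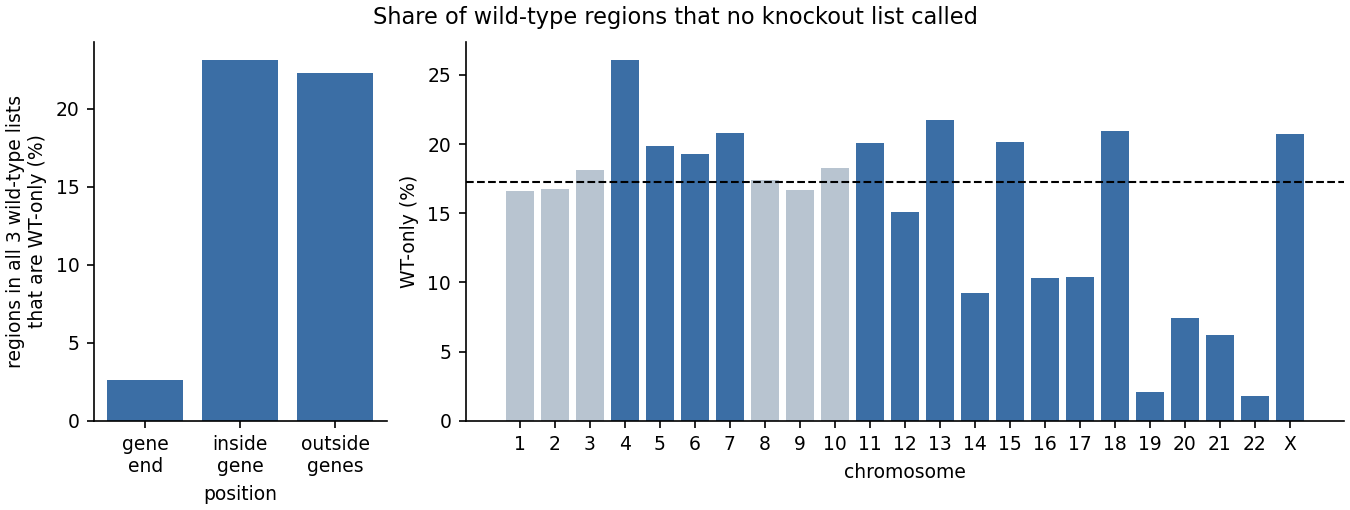
Percentage of the regions called in all 3 wild-type lists that no knockout list called, by position relative to protein-coding genes and by chromosome. Dark chromosome bars have a Benjamini-Hochberg adjusted Fisher's exact p under 0.05 and the dashed line is the genome-wide 17.3%; gene ends stand at 2.64%, chromosome 4 at 26.1% and chromosome 22 at 1.82%.

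Most regions called around CD48 in the full wild-type lists were absent from the knockout lists. CD48 (chromosome 1, 160678746 to 160711822) encodes a surface protein of the SLAM family that binds the receptor CD244 on natural killer cells. Of 6 regions called in all wild-type lists within 50 kb of its ends, 5 were WT-only. A region below the gene, at 160675319 to 160676024, had a wild-type fold of 3.63 ± 0.43 (SD, n = 3). The regions inside the gene, at 160682844 to 160684113 and at 160708528 to 160709524, had wild-type folds of 5.57 ± 0.63 and 6.43 ± 1.22. The regions above it, at 160726322 to 160727069 and at 160739922 to 160741980, had wild-type folds of 5.16 ± 0.16 and 5.51 ± 1.15, and the second of them overlaps the lower end of the neighbouring SLAMF7. The peak at the upper-coordinate end of CD48, where the gene is known to start, was called in all 6 lists, with a fold of 10.3 ± 0.98 in the wild type and 6.16 ± 0.80 in the knockout. Fold values are the authors' own for each list and were lower in the knockout at regions called in all 6 (median 9.19 ± 0.58 against 11.99 ± 1.03), so no change is read from that pair. All 5 of the WT-only regions had folds within 2 times the highest knockout calling threshold of 3.31 in at least 1 wild-type list. With lists of equal length only 1 region near CD48, the peak at its upper end, was still called in all wild-type lists and none was WT-only, so the WT-only calls there rest on the longer wild-type lists.

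**Figure D3:**
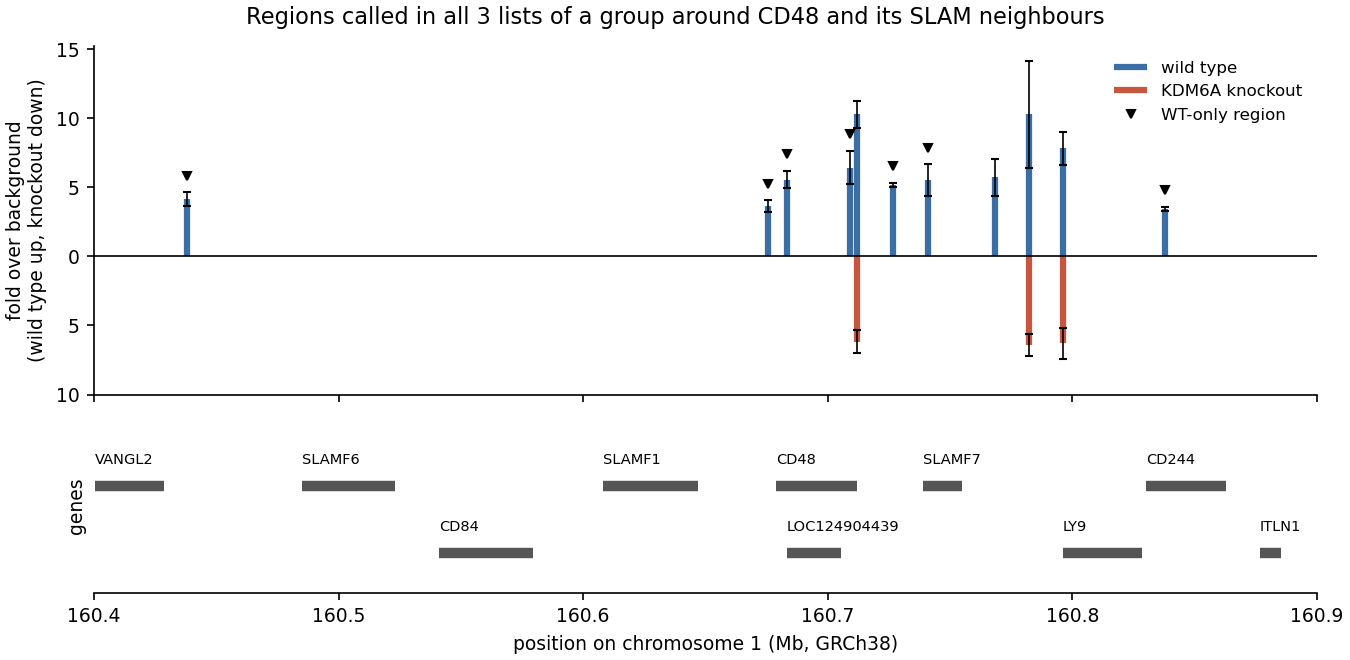
Regions on chromosome 1 from 160.4 to 160.9 Mb that were called in all 3 lists of a genotype, with the mean fold over background in the wild type upward and in the knockout downward (error bars SD, n = 3) above the protein-coding genes. Triangles mark the 7 WT-only regions, 5 of which lie within 50 kb of an end of CD48; the knockout keeps the peak at the upper end of CD48 and regions at 160781985 and 160795526.

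In the full lists and with windows of 1 kb, no ligand of natural killer and T cells had a WT-only gene end. The list of 29 such genes held 10 with a gene-end peak in all 6 lists, among them CD58, MICA, MICB, ULBP3 and CD47, no gene with a WT-only or KO-only end, 9 with a peak in part of the lists and 10 with none. Only 14 of the 29 had a gene-end peak in all 3 wild-type lists, and over all protein-coding genes 1.75% of such ends were WT-only. The absence of WT-only ends is therefore not read as a trait of these ligands. Leaving out a library gave WT-only ends at CD80 (without knockout replicate 3), SLAMF1 (without wild-type replicate 1), and LGALS9 and SLAMF7 (without wild-type replicate 2), genes picked after their values were seen. With all libraries CD80 was also WT-only at the stricter threshold, and LGALS9 with windows of 2 kb. SLAMF7, a SLAM receptor targeted by elotuzumab (chromosome 1, 160739057 to 160754821), had a gene-end peak in 2 wild-type and 0 knockout lists, and 3 of its 7 wild-type regions within 50 kb were WT-only, all of them shared with CD48. The SLAMF7 end became WT-only with windows of 2 kb and was called in 1 wild-type list with windows of 500 bp or lists of equal length, and 6 of 10 regions within 100 kb, but 0 of 3 with lists of equal length, were WT-only. Within 50 kb of the genes of this list 11 of 81 wild-type regions were WT-only (13.6%), against 13.1% of the regions near other genes (adjusted Fisher's exact p = 0.97). The share depended on the setting: within 10 kb it was 7 of 38 (18.4% against 8.41%, Fisher's exact p = 0.037, adjusted p = 0.22). With lists of equal length it was 1 of 53 (1.89% against 4.61%).

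Of the 19 genes of class I presentation 18 had a gene-end peak in all 6 lists, including HLA-B, HLA-C, B2M, TAP1 and NLRC5, the transactivator of class I genes. NLRC5 (chromosome 16, 56989557 to 57083520) had 1 WT-only region among 7, inside the gene at 57014691 to 57015049. Of the 18 genes of class II presentation 4 had a gene-end peak in all 6 lists (CIITA, RFX5, RFXAP and RFXANK), 5 in part of the lists and 9 in none. CIITA, the transactivator of class II genes (chromosome 16, 10866206 to 10943021), had a peak at its upper-coordinate end and further regions inside the gene at 10876548 and 10881212 in all 6 lists, and no WT-only region among 6 (1 without knockout replicate 1 or 3). Its lower-coordinate end had a peak in no list. The windows take both ends of a gene alike, so the gene-end peak of CIITA need not lie at its start. HLA-DRA and CD74 had a gene-end peak in 1 wild-type list and in no knockout list, in no list at the stricter threshold, and with windows of 2 kb CD74 became WT-only. A region inside CD74 at 150409331 to 150411479 was called in all 6. Near class II genes 2 of 32 wild-type regions were WT-only (6.25%) and near class I genes 8 of 69 (11.6%), against 13.1% near other genes (adjusted Fisher's exact p = 0.63 and 0.97). The class II share varied with the library left out, and so did the share near other genes. The class II share was 4 of 32 (12.5% against 15.3% near other genes) without knockout replicate 1. Without knockout replicate 2 it was 5 of 32 (15.6% against 17.5%), and without wild-type replicate 1 it was 6 of 36 (16.7% against 16.5%).

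IRF4, a transcription factor on which myeloma cells depend (chromosome 6, 391752 to 411443), had a gene-end peak in all 6 lists and 3 WT-only regions among 9, at 396104 to 397577, 412119 to 413739 and 414341 to 416139. PRDM1, which drives plasma cell differentiation (chromosome 6, 105992690 to 106109938), had gene-end peaks in 3 wild-type lists and 1 knockout list, and a WT-only region over its lower end at 105992042 to 105992852. Inside PRDM1, 2 regions were called in all 6 lists. The region at 106084306 to 106086836 had a fold of 8.40 ± 0.52 in the wild type and 8.22 ± 1.25 in the knockout. Starts inside a gene record are missed by the gene-end windows, so the gene-end calls do not show that PRDM1 lost an accessible start. CD38, the target of daratumumab (chromosome 4, 15778328 to 15853232), had its gene-end peak in all 6 lists, with a fold of 21.2 ± 2.44 in the wild type and 14.7 ± 1.73 in the knockout, and 1 WT-only region of 6, below the gene at 15771331 to 15772330. The upper-coordinate end of JCHAIN, which encodes the joining chain of secreted IgA and IgM and starts there, was WT-only (wild-type fold 6.40 ± 0.47), but with windows of 500 bp only 2 wild-type lists had the peak. SDC1 (CD138), TNFRSF17 (BCMA) and MYC had gene-end peaks in all 6 lists and no WT-only region within 50 kb when all libraries were used. Leaving out a library gave SDC1 2 of 8 (knockout replicate 3), 1 of 9 (wild-type replicate 2) and 1 of 10 (wild-type replicate 3), and MYC 1 of 3 (knockout replicate 2). Of the 27 plasma cell genes 18 had a gene-end peak in all 6 lists, and 25 of 165 wild-type regions near them were WT-only (15.2% against 13.1%, adjusted Fisher's exact p = 0.63). Within 10 kb 13 of 67 were (19.4% against 8.39%, odds ratio 2.63, Fisher's exact p = 0.0035, adjusted p = 0.067). With lists of equal length 4 of 117 were (3.42% against 4.61%). All 3 calls near IRF4 ended at a fold of at least 4, with 0 of 6. With lists of equal length no region near IRF4, PRDM1, CD38 or NLRC5 was WT-only, and without wild-type replicate 1 the WT-only regions near IRF4 numbered 7 of 13 and near PRDM1 4 of 11. Without wild-type replicate 3 or knockout replicate 1, PRDM1 had 3 of 9 and 2 of 7. CD38 had 2 of 7 without wild-type replicate 1 and 2 of 8 without wild-type replicate 2, and NLRC5 2 of 7 without knockout replicate 1 or 2 and 2 of 9 without wild-type replicate 1. Of the 20 myeloma surface antigens 13 had a peak in all 6 lists and none a WT-only end (1 without knockout replicate 1 or 3 or wild-type replicate 2). Near these antigens 12 of 94 regions were WT-only (12.8% against 13.1% near other genes, adjusted Fisher's exact p = 1). Without wild-type replicate 2 the number was 23 of 107 (21.5% against 16.8%).

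No gene list passed its adjusted test in either direction. The 19 lists, fixed before the data were examined, held 434 different genes, of which 217 had a gene-end peak in all 6 lists, 7 a WT-only end, none a KO-only end, 58 a peak in part of the lists and 152 none. With lists of equal length this split was gone: 3 had a WT-only end (BLNK, HOXA9 and JCHAIN) and 4 a KO-only end (CEBPA, HBA1, MX2 and NCOA6, picked after their values were seen). Leaving out a library gave 7 to 12 WT-only and 0 KO-only ends, and the stricter threshold 9 and 1. Adjusted over the lists, 0 lists passed Fisher's exact test for WT-only or KO-only gene ends or for WT-only or KO-only regions within 50 kb. At an unadjusted p under 0.05 the counts were 0 and 0 for gene ends, 2 for WT-only regions and 1 for KO-only regions. Both of the 2 lists had fewer WT-only regions than other genes: the housekeeping genes 4 of 103 (3.88% against 13.1%, adjusted Fisher's exact p = 0.057) and the interferon response genes 8 of 118 (6.78%, adjusted exact p = 0.38). The housekeeping result passed the adjusted threshold when knockout replicate 1, wild-type replicate 1 or wild-type replicate 2 was left out (adjusted exact p = 0.027, 0.020 and 0.019) and within 100 kb (adjusted exact p = 0.031), and its adjusted exact p reached 1 with lists of equal length. Without knockout replicate 2 the housekeeping share was 8 of 103 (7.77%) and the interferon response share 14 of 118 (11.9%), each against 17.6% near other genes. Without wild-type replicate 2 the interferon response share was 15 of 128 (11.7% against 16.8%). Within 10 kb of the genes the unadjusted results lay on the other side: 4 lists had more WT-only regions than other genes and 0 had fewer, and none passed after adjustment. They were the plasma cell genes and the ligands given above, the stromal markers with 4 of 11 (Fisher's exact p = 0.010, adjusted p = 0.097) and the myeloid markers with 3 of 10 (Fisher's exact p = 0.046, adjusted p = 0.22). The list with unadjusted KO-only regions was that of myeloid markers, with 1 region of 18.

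The remaining WT-only ends of list genes were scattered over lists. They were LHX9, a developmental transcription factor (wild-type fold 5.86 ± 0.70), THEMIS, a T cell signalling protein (5.69 ± 1.34), BLNK, an adaptor of the B cell receptor (7.39 ± 1.04), TRIM22, an interferon-induced antiviral protein (5.80 ± 1.08), ITGAL, the alpha chain of the integrin LFA-1 (3.52 ± 0.32), and HOXA9, a homeobox transcription factor (11.5 ± 1.43). The HOXA9 peak belonged to a wider region that a knockout list also called, and its call ended with windows of 500 bp or 2 kb. With lists of equal length JCHAIN, BLNK and HOXA9 kept 3 wild-type lists against 0, and LHX9, THEMIS, TRIM22 and ITGAL did not. ITGAL also lost its WT-only call at the stricter threshold and at a fold of at least 4. Within windows of 500 bp JCHAIN had a difference of 2 lists in place of 3, which ends its WT-only call. The KMT2 and polycomb complexes, to which KDM6A is tied, had gene-end peaks in all 6 lists at 22 of 22 genes, and the housekeeping genes at 20 of 20. The controls GAPDH and ACTB had no WT-only region among 5 and 8, and ACTB had 1 without knockout replicate 1 or wild-type replicate 3. The other lists had gene-end peaks in all 6 lists at 24 of 46 interferon response genes, 21 of 31 NF-kB genes, 10 of 28 B cell genes, 14 of 25 adhesion and homing genes, 10 of 39 HOX genes, 7 of 38 developmental regulators and 22 of 24 cell cycle genes. Markers of other cell types had gene-end peaks in all 6 lists at 3 of 12 T cell, 1 of 12 myeloid, 2 of 12 erythroid, 2 of 12 epithelial and 1 of 12 stromal genes, and in none at 6, 8, 7, 6 and 9.

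Across all 20037 protein-coding genes, 206 had WT-only ends (1.75% of the 11768 with a peak in all 3 wild-type lists) and 5 had KO-only ends (0.045% of 11032). The direction turned with lists of equal length, where 57 ends were WT-only and 100 KO-only. Of the 206, 182 lay in a region that was itself WT-only, and 24 at the edge of a wider region that a knockout list also called. The highest ranked WT-only ends outside the lists were those of LOC102724117, ACSL5, CFHR4, C1QTNF9B, FBXL7, GOLGA6L4, PTPN22, C7orf78, HOXA10-HOXA9 and SLURP1, and of these only CFHR4, a complement factor H related gene, lay in a WT-only region (chromosome 1, 196888052 to 196918633, wild-type fold 16.4 ± 2.83). The other 9 lost the WT-only call with windows of 500 bp and with windows of 2 kb, where they differed by 0 or 1 list. CFHR4, GOLGA6L4 and C1QTNF9B belong to families of near-identical copies, whose reads were not told apart from those of other copies here. The KO-only ends were those of NPTXR (knockout fold 6.02 ± 1.11), LRRC75B (5.39 ± 1.55) and MLC1 (3.95 ± 0.50), all on chromosome 22, and of GPR39 and the adjoining LOC124905948 on chromosome 2, which share a peak (5.75 ± 0.57). LRRC75B and MLC1 were no longer KO-only under a stricter peak threshold, and the 5 KO-only ends became 23, 12 and 15 without knockout replicate 1, 2 or 3 and 7, 18 and 9 without wild-type replicate 1, 2 or 3.

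The loss was uneven along the genome. Of 23 chromosomes tested, 9 had a higher and 8 a lower WT-only share than the rest (adjusted Fisher's exact test across regions). Chromosome 4 had the highest share, 729 of 2794 regions (26.1%, odds ratio 1.77, adjusted exact p = 4.61e-33), and chromosomes 22 and 19 the lowest, 11 of 603 (1.82%) and 26 of 1230 (2.11%). KO-only regions were over-represented on chromosome 3 (23 of 1627, adjusted Fisher's exact p = 1.1e-06) and chromosome 22 (11 of 573, adjusted exact p = 0.00017). On chromosome 3, 21 of the 23 lay between 12 and 14 Mb, around genes that include PPARG and NUP210, picked after their values were seen. That segment held 347 ± 18 peaks per knockout library and 195 ± 19 per wild-type library. On chromosome 4, the segment from 153 to 171 Mb held 496 ± 52 and 1670 ± 242 peaks, and 240 of its 724 wild-type regions were WT-only (33.1%), against 489 of 2070 on the rest of the chromosome (23.6%). These segments had the highest and the lowest number of knockout peaks relative to the wild type among 11 runs of peak-dense bins (178% and 29.7%). The next lowest was chromosome 11 from 88 to 94 Mb, with 139 ± 11 and 375 ± 68 peaks (37.2%) and 33 of 142 wild-type regions WT-only (23.2%), and the other 8 lay between 62.8% and 97.0%.

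**Figure D4:**
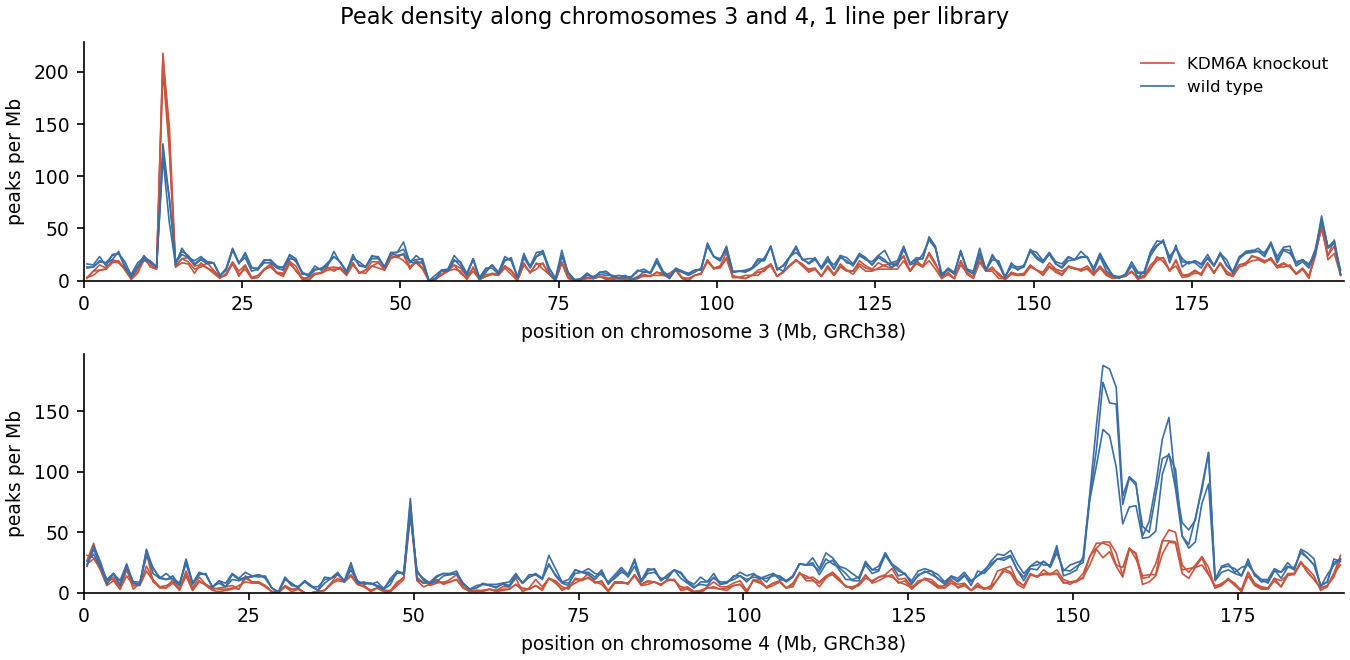
Peaks per 1 Mb along chromosomes 3 and 4 in each of the 6 libraries, wild type in blue and knockout in red. The knockout libraries exceed the wild type between 12 and 14 Mb of chromosome 3, with 202 to 218 peaks against 118 to 131 in the bin that starts at 12 Mb, and the wild-type libraries exceed the knockout between 153 and 171 Mb of chromosome 4.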

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

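All tests in this part were chosen after the results they address were seen.

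The peak on the mitochondrial genome, which no comparison uses, had a higher fold over background in every knockout list than in any wild-type list. Its mean was 16995 ± 350 in the knockout and 15618 ± 547 in the wild type (SD, n = 3).

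WT-only regions outnumbered KO-only regions, 6871 against 95, and 626 of them had a fold of at least 2 times the highest knockout threshold in every wild-type list. The prediction written for lower read depth alone was no more than the 95. That number is the KO-only count at any strength and was not drawn from a model of depth. Of the KO-only regions, 5 had a fold of at least 2 times the highest wild-type threshold in every knockout list. The number of WT-only regions that depth would leave above 2 times the highest knockout threshold was not computed. Setting the 626 against the 95 therefore does not decide on depth. Folds at regions called in all 6 were also higher in the wild type (median 11.99 ± 1.03 against 9.19 ± 0.58, SD, n = 3). Depth, alone or together with a lower enrichment, is therefore not excluded for the 626. For the other 6245 depth and genotype cannot be told apart, since the background pileup differs between the genotypes. Simulated lists without a loss, at each library's background and threshold, gave 43 WT-only regions of 39377, but they took the folds of called wild-type peaks as true and held counting error only, so they do not exclude depth. A uniformly lower enrichment would remove gene ends and other regions of equal strength alike, and the pooled odds within 5 strata of strength were 4.28 times higher away from gene ends. Strength can still differ within a stratum, and region width was not matched. The median width was 792 bp for WT-only regions and 1526 bp for regions called in all 6. The odds therefore do not exclude a lower enrichment. Recovery that depends on base composition may contribute: away from gene ends, chromosomes with more genes per Mb tended to a lower WT-only share (Spearman's rho = −0.41 and Pearson's r = −0.57 across 23 chromosomes, permutation p of rho 0.052), and it cannot be told apart from a genotype effect without a genome sequence. With 10 splits of the 6 libraries a share under 0.05 is out of reach; the real split gave 6966 regions and 211 genes called in 1 group only (1 of 10 splits each), and the highest other split 360 and 31.

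The peak-dense segments of chromosomes 3 and 4 may differ in DNA copy number between the knockout and wild-type cells. Relative to the rest of chromosome 4, regions called in all 6 lists between 153 and 171 Mb had a log2 fold that was 0.21 lower in the knockout (log2 difference −0.21), with −0.30 at 31 gene ends and −0.17 at 224 other regions. Between 12 and 14 Mb of chromosome 3 the log2 difference was 0.66, with 0.52 at 11 gene ends and 0.73 at 65 other regions. In each of these comparisons every knockout list lay on the same side of every wild-type list, which a copy number difference needs (exact permutation p = 0.1, the smallest possible). The measure over all shared regions is not specific to these segments, since of 11 runs of peak-dense bins it set the genotypes apart at 7, 5 of them rises on other chromosomes. Of those 5 only the run on chromosome 2 from 9 to 14 Mb held gene ends called in all 6 lists. There the log2 difference was 0.18 at 31 gene ends and 0.34 at 280 other regions. The runs on chromosomes 1 (122 to 125 Mb), 5 (47 to 50 Mb), 7 (58 to 60 Mb) and 12 (35 to 37 Mb) held no such gene end. The comparison of gene ends with other regions could therefore not be made there. No regions prone to mapping artifacts were left out of the 11 runs. Whether the peaks of these runs mark accessible chromatin was not tested. On chromosome 11 from 88 to 94 Mb, the third segment picked, the log2 difference was −0.10 over 57 regions called in all 6 lists. It was −0.33 at 6 gene ends, where the genotypes were apart, and −0.02 at 51 other regions. Over all 57 regions and at the 51 the lists of the genotypes overlapped, so what a copy number difference needs was not met there. With no DNA copy number measured, a chromatin domain that opens or closes gene ends and other regions together stays open as an explanation for chromosomes 3 and 4.

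In the full lists, more regions around CD48 were WT-only than regions of matched peak strength predict. Regions matched on wild-type strength and on lying at a gene end predicted 1.55 WT-only regions of 6 where 5 were found (exact p = 0.0015, adjusted p = 0.024 over the 16 fixed genes). This exact p takes the 6 regions as independent, which regions of 1 locus are not, so it can overstate the excess. Of 3160 genes with at least 6 wild-type regions within 50 kb only CD48 and LOC124904439, which lies inside it, had so high a share. The cut of 6 is the count of CD48 itself, and this ranking was not matched for strength. The next shares were 5 of 7 near PICALM and 5 of 7 near SCYL3. Loss of a part of chromosome 1 that reaches 2 Mb to either side would raise the share there, but outside 160.4 to 160.9 Mb 11 of 92 regions were WT-only (11.96%, 95% Wilson interval 6.81% to 20.2%), against 17.3% in the rest of the genome. Lower read depth cannot be told apart from the genotype here, because 0 of the 5 CD48 regions lay above 2 times the highest knockout threshold in every wild-type list, and with lists of equal length 0 regions were WT-only and 1 was left in all wild-type lists. A genotype effect on the CD48 neighbourhood is a hypothesis that these lists leave open.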

How the results depend on the processing

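The fold threshold of 4, the 2 kb windows, the exclusion of peak-dense bins and the strata for chromosomes and region classes were chosen after seeing the data. So were the requirement that the region itself be called in 1 genotype only and the counts near the fixed genes and of list genes under other settings. The same holds for every alternative given for the KDM6A peak and for the odds away from gene ends. Peak number, covered length, gene-end share and the Jaccard difference kept their direction in every alternative, except that equal list length sets the difference in peak number to 0 by construction; KDM6A kept its peak in 6 lists and the odds away from gene ends ranged from 4.28 to 16.8. With equal list length 1961 regions and 57 gene ends were WT-only and 906 and 100 KO-only, so that the direction turned for gene ends. Calling in at least 2 lists of a group and none of the other gave 13578 and 425 WT-only, and 567 and 40 KO-only. KO-only counts were small and moved under more settings than WT-only counts: 157 regions and 12 gene ends at a fold of at least 4, 241 regions with windows of 500 bp around summits, and 9 gene ends at a −log10 q-value of at least 5. Leaving out 1 library gave 157 to 316 KO-only regions and 7 to 23 KO-only gene ends, since fewer lists must hold or lack a peak, and 7907 to 9541 WT-only regions. Lists past the adjusted test for regional loss numbered 0 to 1 with a library left out and 1 within 100 kb, always the housekeeping genes with fewer WT-only regions, and with strength strata 1 list passed for regional gain, the myeloid markers with 1 region; for those the cause was not tested. Near CD48 the WT-only regions numbered 5 of 6, 4 of 5 at the stricter q-value or a fold of at least 4, 3 of 4 within 10 kb, 5 of 9 within 100 kb, and 0 of 1 with lists of equal length, which drop the weaker wild-type peaks. Chromosomes past the test numbered 13 to 21 against 17. The overlap of at least 50% is met by every peak of a merged region, so it changes nothing.

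The replicate numbers did not pair the libraries: the deviations of libraries with the same number correlated at −0.0049, 0.0010 and −0.023. With the number as a replicate block, the mean differences were −19512 peaks, −21.8 Mb and 9.04 percentage points, as without it, each with an exact sign-flip p of 0.25, the smallest that 3 pairs allow.

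Not run, for want of strand or genome sequence, were windows of 2 kb upstream to 500 bp downstream, windows at all transcript starts, and every motif and base composition alternative. Depth limits which losses can be called: in simulated lists a 2-fold loss was called in 15.5% of 200 regions and a 4-fold loss in 55.5%.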

Other observations

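The regions described here were picked after their values were seen. Away from the peak-dense bins, the WT-only regions with the highest fold lay mostly far from gene ends. They included a region on chromosome 13 at 109547460 to 109548913 (wild-type fold 18.95 ± 1.86, SD, n = 3), 204509 bp from the nearest end of IRS2, an adaptor of insulin signalling. A region inside EPHA4, an ephrin receptor, on chromosome 2 at 221548828 to 221549896 had a wild-type fold of 17.1 ± 2.93. A region inside FBN2, a fibrillin of the extracellular matrix, on chromosome 5 at 128425885 to 128426896 had a fold of 15.2 ± 1.80, and a region on the same chromosome at 158398111 to 158399425, 297153 bp from the nearest end of EBF1, a B cell transcription factor, had 12.8 ± 0.32. Of the 626 WT-only regions with a fold of at least 6.62 in every wild-type list, 21 lay at a gene end, 223 inside genes and 382 outside genes, and 620 lay outside the peak-dense bins.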
